A study of Mus musculus with 6 samples.

How the data were processed

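Total RNA from the fundic gastric mucosa, in 3 wild type and 3 Lasp1 knockout samples, was labelled with biotin and hybridised to Illumina arrays, per the labels. The labels' protocols name an RNA tissue kit and the Ambion MessageAmp kit for the labelled cRNA. The values used are the deposited intensity table of the series: 1 linear probe intensity per array for 45281 probes. From the values themselves, each column has a median of 1000 and no value below 541.9, so the authors scaled every array to that median and the background had not been subtracted. Undoing the scale put all dim values back on steps of 0.05 (tolerance 0.02 of a step), with unscaled medians of 50.75 for wild type replicate 3 to 64 for wild type replicate 1. The sorted columns differ, so the arrays had not been quantile normalized. The scanner, its software, the background step and any filter are not given in the sources used here, nor is a genome build.

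Depth on an array is signal over background. Probes above the brightest Y-linked probe of the same array, taken as background because all samples read as female, made up 35.8% of probes on wild type replicate 3 and up to 48.5% on knockout replicate 1. Background was thus near 1000 on every array, and folds of dim probes are understated because it was not subtracted.

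Probes were named from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Probes with several symbols or none were tested and left unnamed. Of the named probes, 34807 matched the GRCm38.p6 gene table by gene identifier, which was used for names and for gene order only.

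The samples were grouped by genotype from their source labels. Intensities were kept as the authors scaled them, floored at 16 (no value was that low) and log2 transformed. Probes whose mean log2 value over the 6 arrays lay above that of the median probe were kept, 22640 probes with a mean intensity above 991, covering 11868 named genes. Knockout was compared with wild type using lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all kept probes. A gene with several probes is given by its brightest. All log2 differences are knockout minus wild type. Single genes also had an exact permutation test, for which 3 against 3 arrays cannot go below 0.1. On simulated data with the mean and spread of these 22640 probes, the test called 55 of 100 probes changed 2-fold and 97 of 100 changed 4-fold, with 4 false calls. The simulated noise was normal and independent between probes, without the differences between arrays that many real probes share. These rates may therefore not hold for the real arrays.

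Gene lists for cell types, neighbouring tissues, pathways and the neighbourhood of Lasp1 were fixed before the data were examined. The 32 with at least 3 kept members were tested with camera (preset correlation 0.01, 1 probe per gene), with an estimated correlation, and with fry. The 2 other lists, of Xist and of Y-linked genes, checked the sex of the samples. The genes named follow a rule fixed beforehand. It took Lasp1 and the genes past the threshold with non-overlapping groups. These were filled up to 8 in each direction by the smallest unadjusted p, whether or not the groups overlapped. The rule also took up to 4 members of smallest p of each list named, and 13 lineage and partner genes. Some lists have fewer members named, or none. Genes that set arrays apart, genes around Lasp1 outside these, and genes of the comparison by title number were chosen after their values were seen.

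The replicate numbers were tested for pairing before the fits were compared. Alternatives fixed beforehand were median scaling, quantile and cyclic loess normalization, other filters, floors and offsets, other variance models, array weights, a replicate block, the title number as a covariate, the mean of a gene's probes, leaving out each array, and other thresholds and list tests. After seeing the data, 5 were added: leaving out both arrays with squamous transcripts, squamous and pancreatic scores as covariates, background correction of the unscaled values with normexp followed by quantile normalization, a block for arrays numbered 1 to 3 against 4 to 6 in their titles, and an estimated correlation for the lists under each alternative. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.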

Results

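The study asked how deletion of Lasp1 alters mRNA levels in the lining of the stomach. Lasp1 encodes an actin-binding protein with a LIM and an SH3 domain, which is abundant in the acid-secreting parietal cells. Total RNA from the fundic gastric mucosa of mice aged 3 months was measured on 6 Illumina bead arrays, 3 from wild type mice and 3 from Lasp1 knockout mice. Each array carried 45281 probes, and the authors' intensities had a median of 1000 on every array. Xist, the transcript of the inactive X chromosome, was bright on all 6 arrays (55746 to 88070), and the 9 probes of Y-linked genes stayed at or below 1212, so every sample read as female. The number of arrays limits the precision of every comparison. The labels do not say that each array held a separate mouse, so the p-values measure the spread between these samples.

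The arrays differed in ways the groups did not follow. The array of wild type replicate 3 stood apart on the first principal component (59% of the variance), with Pearson correlations across probes of 0.959 to 0.980 to the knockout arrays and 0.969 to the other wild type arrays. It carried high levels of pancreatic acinar transcripts: Cpa1, a carboxypeptidase of the exocrine pancreas, read 449183 there and at most 6865 elsewhere. Knockout replicate 3 carried them at lower levels: Cela2a, an elastase, read 58913 there, 647587 on wild type replicate 3 and at most 2400 on the other 4 arrays. Wild type replicate 2 and knockout replicate 1 carried transcripts of squamous epithelium, such as Lor, the cornified envelope protein loricrin (274920 and 399114, at most 10048 elsewhere). Knockout replicate 1 was also high in smooth muscle transcripts, with Myh11, the smooth muscle myosin heavy chain, at 23458 against at most 5590. Arrays numbered 1 to 3 in their titles (wild type replicates 1 and 2, knockout replicate 1) differed from those numbered 4 to 6 in 164 of 22640 probes by limma with the genotype in the model. Acot1, an acyl-CoA thioesterase, read 33706 to 50752 on the first set and 2573 to 3588 on the second. The labels do not say what this number means. Because both genotypes occurred in both sets, values with the set as a block and within each set are given beside Lasp1, the probes at or near the threshold and the lists that passed. Some other genes have values within each set. Each within-set difference rests on 1 array of one genotype and was not tested. That array is knockout replicate 1 among those numbered 1 to 3, and wild type replicate 3 among those numbered 4 to 6. Both carried transcripts of other tissues, as given above, so a within-set value may reflect that array alone.

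**Figure D1:**
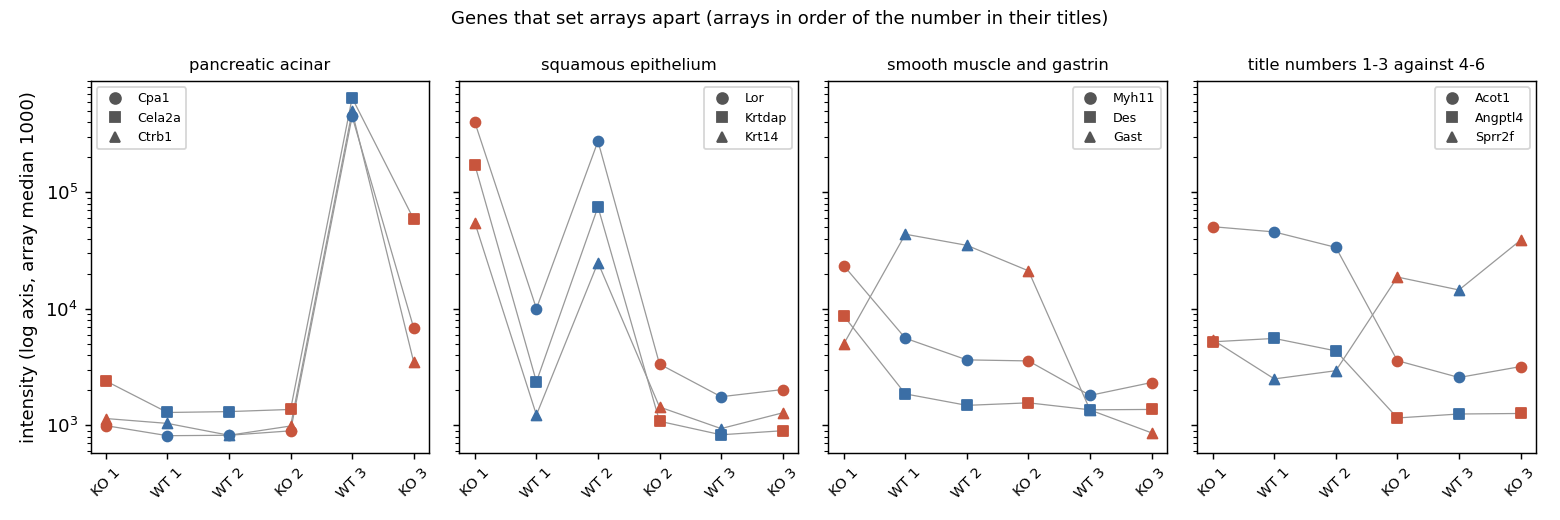
Intensity on a log axis (array median 1000) of 3 genes per panel on each of the 6 arrays, ordered by the number in their titles, with wild type (WT) in blue and Lasp1 knockout (KO) in red. Pancreatic genes peaked on WT 3 (Cpa1 at 449183), squamous genes on KO 1 and WT 2 (Lor at 399114 and 274920), and Acot1 was higher on all arrays numbered 1 to 3 than on those numbered 4 to 6.

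Lasp1 itself was lower on every knockout array, and signal well above background remained. Its brightest probe, ILMN_2879746, read 241114 ± 55289 in wild type and 96449 ± 12620 in knockout mucosa (mean ± SD, n = 3 each), a log2 difference of -1.30 (SE 0.21), or 40.6% of the wild type level. A second probe, ILMN_2879745, read 24876 ± 10242 and 7736 ± 997, a log2 difference of -1.59 (SE 0.34) and 33.3% of wild type. A further, dim probe, ILMN_2596851, lay near background in both groups (1189 ± 264 and 1018 ± 139, log2 difference -0.21). For both bright probes all 3 knockout arrays lay below all 3 wild type arrays, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 arrays can give. Neither passed the limma test over all probes (adjusted p = 0.994, unadjusted p = 0.000412 and 0.0024). With the title-number set as a block the brightest probe differed by -1.23 (adjusted p = 0.399), and it differed by -1.62 within the arrays numbered 1 to 3 and by -0.83 within those numbered 4 to 6. It passed with array weights (log2 -1.45, adjusted p = 0.00222), with cyclic loess normalization (-1.48, adjusted p = 0.0491) and with squamous and pancreatic scores as covariates (-1.47, adjusted p = 0.0365), within a range of 0.00222 to 1 over all alternatives. The fit with array weights rests largely on wild type replicate 2, with a weight of 38.8 against at most 1.6 on any other array. Leaving out wild type replicate 3 took ILMN_2879745 past the threshold (limma adjusted p = 0.0317). The positions of these probes relative to the deleted part of the gene are not given in the sources used here, so they may not all check the deletion.

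Over the whole array, 2 of 22640 probes passed the threshold, both higher in the knockout. Elobl, an elongin B-like gene, was at background in wild type (830 ± 27) and read 3483 ± 383 in knockout mucosa (n = 3 each), a log2 rise of 2.06 (SE 0.13, 4.18-fold, limma adjusted p = 0.0153). A probe without a gene name in the table used here, ILMN_2993962, rose from 880 ± 4 to 3444 ± 395 (log2 1.96, SE 0.13, 3.90-fold, limma adjusted p = 0.0153). The 2 probes read nearly the same on every array. Elobl read 802, 856 and 832 on wild type replicates 1 to 3, and ILMN_2993962 read 876, 879 and 885. On knockout replicates 1 to 3 they read 3749, 3044 and 3657, and 3766, 3004 and 3561. Whether both read 1 transcript was not tested, so the 2 calls may not be separate changes. All 3 knockout arrays lay above all 3 wild type arrays for both. Pigr, the receptor that carries polymeric immunoglobulins across epithelia, read 2731 ± 110 and 8057 ± 913 (log2 1.56, SE 0.13, 2.94-fold) and missed the threshold (adjusted p = 0.0537), with separated groups.

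With the title-number set as a block, 3 probes passed: Elobl (log2 2.09, adjusted p = 0.0127), ILMN_2993962 (1.99, adjusted p = 0.0127) and Pigr (1.51, adjusted p = 0.0478). After quantile normalization with the same block 2 passed, and Pigr did not (adjusted p = 0.0785). Within the arrays numbered 1 to 3 and within those numbered 4 to 6 the log2 differences were 2.18 and 2 for Elobl, 2.10 and 1.89 for ILMN_2993962, and 1.36 and 1.66 for Pigr. Both calls were lost on leaving out any array but wild type replicate 3. Elobl then gave an adjusted p of 0.139 without wild type replicate 1, 0.275 without wild type replicate 2, and 0.12, 0.0807 and 0.254 without knockout replicates 1, 2 and 3, at log2 differences of 2.01 to 2.16. The replicate number as a block also ended them (Elobl adjusted p = 0.0711, range over all alternatives 0.00012 to 0.819), and 1816 probes passed with array weights.

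**Figure D2:**
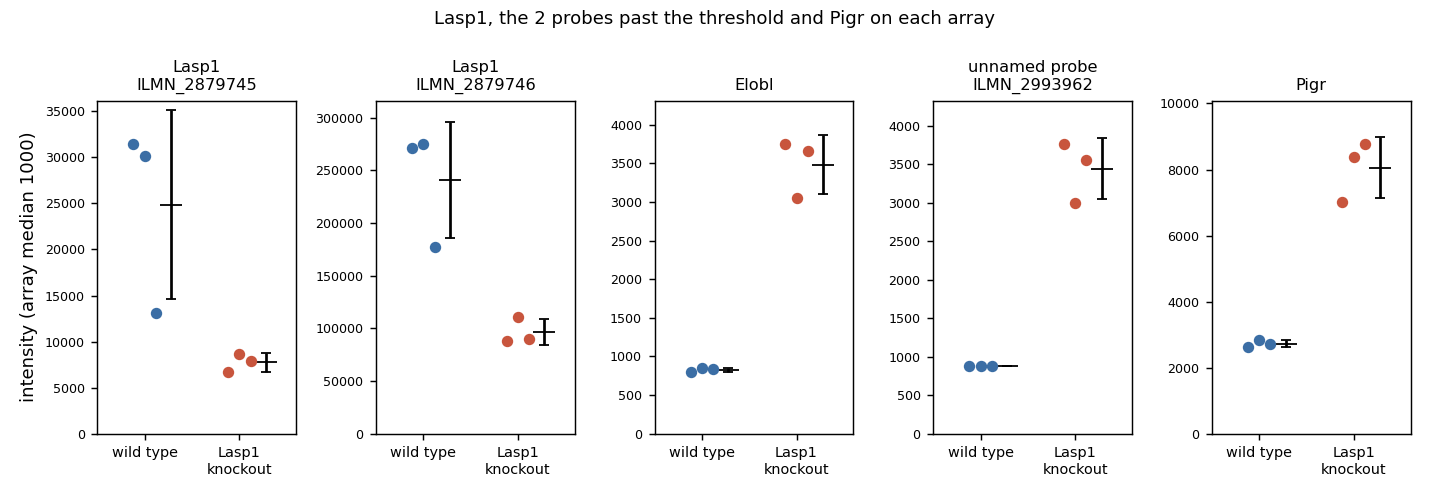
Intensity (linear axes from 0, array median 1000) of both bright Lasp1 probes, the 2 probes past the threshold and Pigr on each array, wild type in blue and Lasp1 knockout in red, with the mean and SD of each group (n = 3) beside the points. The groups do not overlap in any panel, and Elobl moves from 830 ± 27 to 3483 ± 383.

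The remaining genes named by the fixed rule did not pass the threshold (adjusted p = 0.994 for each), although their groups did not overlap. On the higher side were Bpifb1, a secreted lipid-binding protein of mucosal surfaces, with a log2 difference of 1.85 (SE 0.41) on each of its 2 probes, and Scd1, the stearoyl-CoA desaturase, with 1.10 (SE 0.23). Sftpd, the collectin surfactant protein D, differed by 0.88 (SE 0.16), the antiviral enzyme gene Oas2 by 0.81 (SE 0.16), Smarce1, a subunit of the SWI/SNF chromatin remodeller, by 0.67 (SE 0.15) and the sulfotransferase Sult4a1 by 0.61 (SE 0.12). On the lower side, Zg16, a lectin of secretory granules, differed by -3.30 (SE 0.78). It read 86169, 124704 and 560890 on the wild type arrays and 38479, 17105 and 9651 on the knockout arrays. Without wild type replicate 3, the array high in pancreatic transcripts, its difference was -2.48. Rapgefl1 differed by -0.77 (SE 0.22) on its brightest probe and by 0.24 on the other. Further down were 2210409E12Rik (-0.66), Acsl6 (-0.47), Gadd45g (-0.42), Sel1l (-0.34), Hsd17b14 (-0.32) and Nup210 (-0.32). Because their groups did not overlap, the genes in this paragraph could not turn sign within the title-number sets, so the shared direction adds no evidence. Some varied in size. Zg16 differed by -1.43 and -5.45, Scd1 by 1.63 and 0.54, Acsl6 by -0.08 and -0.79 and Sel1l by -0.06 and -0.60.

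At an unadjusted p under 0.05 there were 392 probes, where 1132 are expected by chance, and 7.19% of probes had non-overlapping groups, where chance gives 10%. Of the 392, 368 were higher in the knockout and 24 lower. The median log2 difference over all tested probes was 0.10 in the deposited values and 0.0029 after quantile normalization, under which 214 probes were higher and 168 lower. Single arrays also moved it: without wild type replicate 3 the median was -0.0039 (210 probes higher, 127 lower), and without wild type replicate 1 it was 0.20 (1215 higher, 17 lower).

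Differences of gene lists are therefore given with that shift of 0.10 in mind. Of 32 lists fixed before the data were examined, 11 passed camera with its preset correlation, 6 higher and 5 lower in the knockout relative to other genes. None passed with an estimated correlation (adjusted p of 0.67 or more for each), and none passed with fry, which tests whether a list moves on balance in 1 direction. With the title-number set as a block none passed these tests either (adjusted p of 0.424 or more with an estimated correlation and 0.179 or more with fry). No list member passed over all probes, and calls adjusted over the list alone are named below.

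Interferon-response genes were higher on average: all 18 measured members, 0.42 log2 at the median (15 members and 0.29 after quantile normalization, camera adjusted p = 1.24e-06, adjusted p = 0.67 with an estimated correlation). The 4 members of smallest p were Oas2 (0.81), Oasl2 (0.67), Ifit3 (0.46) and the GTPase Igtp (0.78), and Oas2 alone passed when adjusted over the list alone (adjusted p = 0.0312). The list median was 0.44 within the arrays numbered 1 to 3 and 0.44 within those numbered 4 to 6, where all probes had medians of 0.04 and 0.29, and the camera adjusted p with the set as a block was 0.000282.

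Immediate early genes, which respond within minutes to stimulation, were higher for 18 of 19 members, with a median of 0.47 (16 members and 0.20 after quantile normalization, camera adjusted p = 1.31e-06, adjusted p = 0.67 with an estimated correlation). Jun (0.72), Egr1 (0.89), Zfp36 (0.60) and Junb (0.68) had the smallest p-values, and none passed when adjusted over the list alone. The list medians within the title-number sets were 0.29 and 0.62, and the blocked adjusted p was 0.00869. The median of the immediate early genes was 0.29 without knockout replicate 1, 0.30 without knockout replicate 2 and 0.16 with array weights. All 6 MHC class II genes, which present antigen, were higher, with a median of 0.55 (0.38 after quantile normalization, camera adjusted p = 0.000172, adjusted p = 0.67 with an estimated correlation). Cd74 (0.65), H2-Aa (0.64), H2-Ab1 (0.64) and H2-Eb1 (0.46) led that list, which had medians of 0.73 and 0.48 within the title-number sets (0.64 and 0.08 after quantile normalization, blocked adjusted p = 0.00463). The MHC class II call ended without both arrays with squamous transcripts (median 0.32, adjusted p = 0.208). Of 10 mast cell genes 9 were higher, with a median of 0.49 (camera adjusted p = 0.00432, adjusted p = 0.733 with an estimated correlation). The mast cell protease Mcpt1 differed by 1.49 (SE 0.35, 2.81-fold) and passed when adjusted over the list alone (adjusted p = 0.0359). The proteases Cpa3 (0.93), Tpsb2 (0.85) and Cma1 (0.49) did not. Medians of the mast cell list within the title-number sets were 0.35 and 1 (blocked adjusted p = 0.0164), and leaving out wild type replicate 3 lowered its median to 0.15 (adjusted p = 0.0221). With array weights the mast cell call ended (adjusted p = 0.223).

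Genes of cholesterol and fatty acid synthesis were higher for all 14 members, with a median of 0.31 (13 members and 0.17 after quantile normalization, camera adjusted p = 1.77e-05, adjusted p = 0.67 with an estimated correlation). Scd1 (2.15-fold) passed when adjusted over this list alone (adjusted p = 0.0282), and Elovl6 (0.58), Fdps (0.56) and Lss (0.44) did not. The list did not pass with the title-number set as a block (adjusted p = 0.056), and its medians were 0.02 within the arrays numbered 1 to 3 and 0.52 within those numbered 4 to 6. Without knockout replicate 1 its median was 0.48. Actin cytoskeleton and focal adhesion genes, the setting in which Lasp1 acts, were higher for 27 of 30 members, with a median of 0.22 (24 members and 0.11 after quantile normalization, camera adjusted p = 0.0102, adjusted p = 0.983 with an estimated correlation). Csrp1 (0.49), Pfn1 (0.59), Tpm3 (0.40) and Myl12a (0.22) led this list, and none passed when adjusted over the list alone. Its medians within the title-number sets were 0.05 and 0.68 (-0.03 and 0.30 after quantile normalization, blocked adjusted p = 0.0164). The median was 0.35 without wild type replicate 1, and the call ended without wild type replicate 3 (median 0.07, adjusted p = 0.336) and without knockout replicate 2 (median 0.15, adjusted p = 0.15), with array weights (0.523) and with the covariates (0.257).

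Pancreatic acinar genes were lower in the knockout for 15 of 16 members, with a median of -1.70 (camera adjusted p = 9.84e-14, adjusted p = 0.67 with an estimated correlation). This rested on wild type replicate 3: without it the median was 0.70 (adjusted p = 0.208), with knockout replicate 3 then the array of highest Cela2a (58913) and Cpa1 (6865). Without wild type replicate 1 or 2 the median was -2.91 or -3.03, and with the title-number set as a block it was -3.24, from 0.09 within the arrays numbered 1 to 3 and -6.16 within those numbered 4 to 6. Rnase1 (-1.49), Cela1 (-1.85) and Try4 (-1.69) followed Zg16 in this list. Chief cell genes passed as lower although 6 of 10 members were higher, with a median of 0.02 and a mean of -0.40 (camera adjusted p = 0.00428, adjusted p = 0.67 with an estimated correlation). The members that moved most were Cpb1 (-2.16) and Rnase1 (-1.49), both also in the pancreatic acinar list, and Bhlha15 (-0.51). Whether Bhlha15 followed the pancreatic transcripts was not tested. Without wild type replicate 3 the chief cell list had a median of 0.06 (adjusted p = 0.867), without knockout replicate 1 an adjusted p of 0.341. The call also ended after quantile normalization (0.191, and 0.19 with normexp), with no filter on dim probes (0.162) and with the covariates (0.745), of which the pancreatic score shares Rnase1 and Cpb1 with this list. Its adjusted p with the title-number set as a block was 3.92e-06 (0.424 with an estimated correlation), with medians of -0.03 and -0.05 within the sets.

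Circadian clock genes had a median of -0.10 (camera adjusted p = 0.000295, adjusted p = 0.67 with an estimated correlation), with Per1, a light- and feeding-responsive clock gene, at -0.79 (SE 0.36). After quantile normalization their median was -0.21, with 2 of 15 members higher (camera adjusted p = 0.00502, 0.781 with an estimated correlation). Medians within the title-number sets were -0.07 and 0.03 (blocked adjusted p = 0.00474, and 0.0522 after quantile normalization). Without wild type replicate 1 the circadian median was 0.11, and the call ended without knockout replicate 2 (median 0.01, adjusted p = 0.143), with array weights (0.159) and with no filter on dim probes (0.0828). Fatty acid oxidation genes had a median of -0.03 and a mean of -0.20, and a median of -0.185 with 3 of 15 members higher after quantile normalization (camera adjusted p = 0.000295 as deposited, adjusted p = 0.67 with an estimated correlation). That call ended with the title-number set as a block (median 0.18, adjusted p = 0.36), and the medians within the sets were -0.0015 and 0.29. The fatty acid oxidation median moved with single arrays. It was -0.27 without wild type replicate 3 and -0.17 without knockout replicate 1. It was 0.06, 0.05 and 0.04 without wild type replicates 1 and 2 and knockout replicate 3, where all probes had medians of 0.20, 0.12 and 0.13. Relative to other genes the list was still lower in these last fits (camera adjusted p = 0.00382, 0.0246 and 0.00438 with the preset correlation). Enteroendocrine genes passed as lower with a median of 0.03 and a mean of -0.06 (camera adjusted p = 0.0366, adjusted p = 0.733 with an estimated correlation). Gast, the gene of the hormone gastrin, read 43741, 35100 and 1354 on the wild type arrays and 5003, 21207 and 861 on the knockout arrays. The enteroendocrine call ended without wild type replicate 3 (adjusted p = 0.507), without knockout replicates 1 and 2 (adjusted p = 0.604 and 0.265) and after quantile normalization (adjusted p = 0.488), and in 11 of 23 alternatives in all. With the title-number set as a block the adjusted p was 0.00463 (0.86 with an estimated correlation, 0.0916 after quantile normalization), at medians of -0.09 and 0.17 within the sets.

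**Figure D3:**
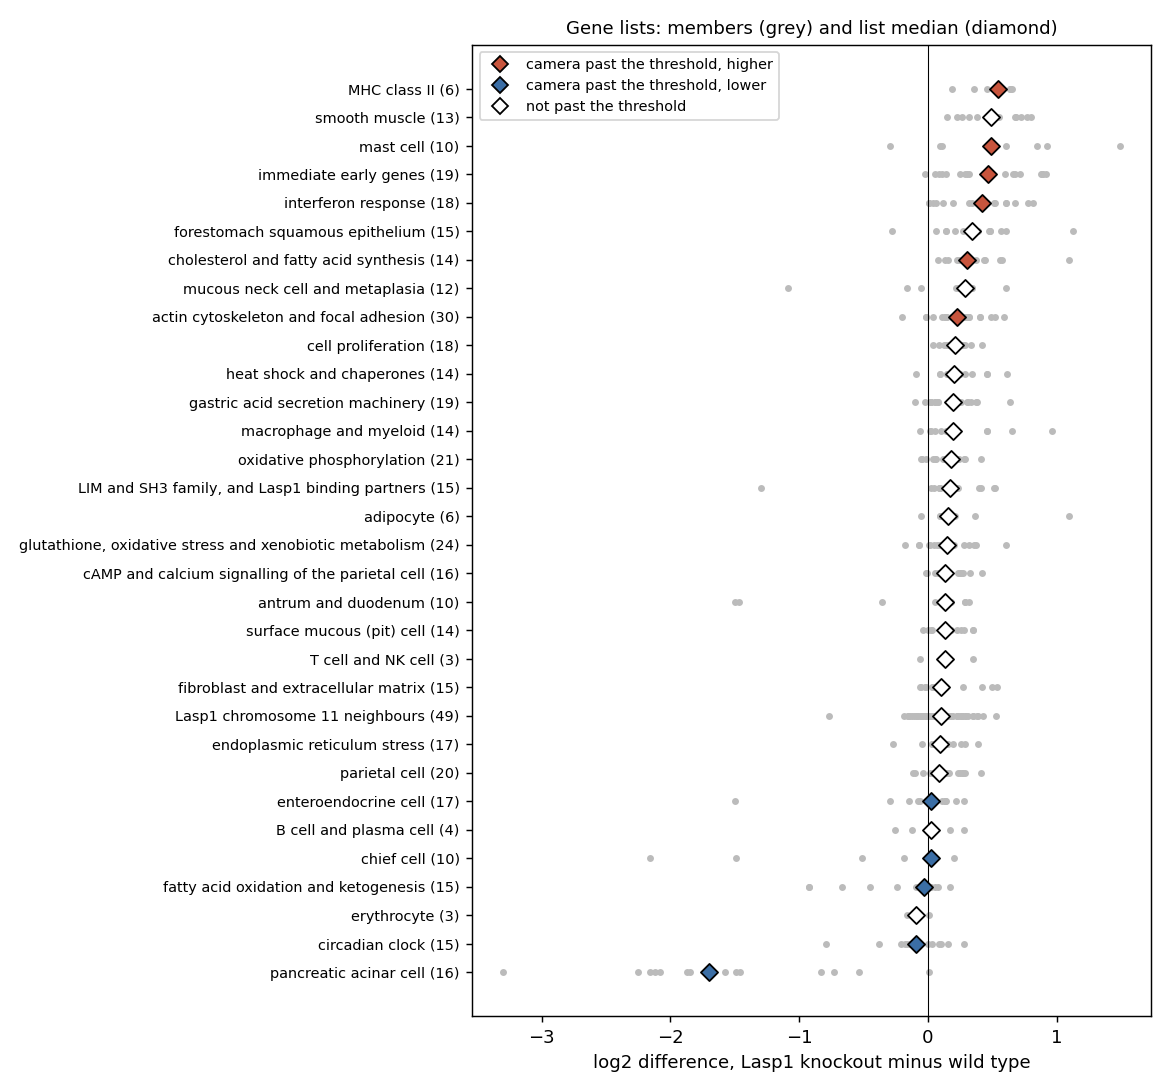
Log2 difference between Lasp1 knockout and wild type for the members of each gene list (grey points, number of measured members in brackets) and the list median (diamond), filled where camera with its preset correlation passed the threshold. Medians run from -1.70 for pancreatic acinar genes to 0.55 for MHC class II, and the median over all probes was 0.10.

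None of the genes named here passed the test, and differences in markers of the main gastric cell types were small or came with wide intervals. Of the parietal cell genes, Atp4a and Atp4b, the subunits of the gastric proton pump, differed by 0.06 (95% interval -0.27 to 0.38) and 0.01 (-0.28 to 0.31). Pgc, the chief cell pepsinogen C, differed by 0.06 (-0.24 to 0.36) and Cblif, gastric intrinsic factor, by 0.03 (-0.23 to 0.30). The mucins differed by 0.11 for Muc5ac of surface cells and 0.30 (-0.46 to 1.06) for Muc6 of neck cells, and Tff2, a trefoil peptide, by -0.05. Chga, a marker of endocrine cells, differed by -0.15 (-0.76 to 0.46) and Hdc, the histamine-forming enzyme, by -0.29 (-0.65 to 0.07). Within the title-number sets Muc6 differed by 0.10 and 0.94, Chga by -0.67 and 0.17, and Hdc by -0.53 and -0.05. With the set as a block after quantile normalization these genes differed by 0.25, -0.535 and -0.565 (limma adjusted p of 0.769 or more). Atp4a, Atp4b, Pgc, Cblif, Muc5ac and Tff2 were among the brightest probes (313608 to 613674), where the array's range may compress differences. Of the relatives and partners of Lasp1, Nebl (0.08) lay at background, and Vasp, Zyx and Lpp differed by 0.05, 0.23 and 0.42, none past the threshold. The 4 other Lpp probes ran from -0.14 to 0.47. The parietal cell list had a median of 0.09 over 20 genes, led by Cldn18 (0.42), the acid secretion machinery 0.20 over 19, cAMP and calcium signalling 0.14 over 16 and the Lasp1 family and partners 0.17 over 15, of which Lasp1 alone passed when adjusted over the list alone (adjusted p = 0.00618).

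Further lists that did not pass were those of surface mucous cells (median 0.13, led by Gkn1 at 0.35), mucous neck cells and metaplasia (0.29), antrum and duodenum (0.14), smooth muscle (0.49), forestomach squamous epithelium (0.35), fibroblasts (0.10) and adipocytes (0.15). Scd1, counted above in the cholesterol and fatty acid list, is also in the adipocyte list and alone passed when adjusted over that list. Of the blood cell lists, macrophages had a median of 0.20, T and NK cells 0.13, B and plasma cells 0.02 and erythrocytes -0.09. Heat shock genes had a median of 0.21, endoplasmic reticulum stress 0.09, cell proliferation 0.21, oxidative phosphorylation 0.18, and glutathione and xenobiotic metabolism 0.15. Smooth muscle and the glutathione list passed camera with the title-number set as a block (adjusted p = 4.37e-06 and 0.0108), but not with an estimated correlation (0.86 for both) or with fry (0.319 for both). Smooth muscle had medians of 1.48 within the set that holds knockout replicate 1 and 0.25 within the other.

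Several of these lists passed camera with its preset correlation when the processing or the arrays were altered. With an estimated correlation, a test added after seeing the data, no list passed under any of the 23 alternatives (lowest adjusted p = 0.292, among the brightest 25% of probes), so the calls in this paragraph rest on the preset correlation. Smooth muscle genes were higher after quantile normalization (adjusted p = 0.00854, 0.889 with an estimated correlation), with cyclic loess (0.00991), with normexp (0.0121), with the replicate block (0.00159), with the title number as a covariate (2.32e-08) and without knockout replicate 2 or 3 (0.000189 and 0.000161). Without knockout replicate 1, the array with the highest Myh11, they were lower (median -0.09, adjusted p = 0.0109), as they were without both squamous arrays (-0.06, 0.0323). Forestomach squamous genes were lower without knockout replicate 1 (median -0.80, adjusted p = 0.000145) and without wild type replicate 1 (-0.01, 0.00382) and with array weights (-1.99, 1.36e-08), and higher without wild type replicate 2 (1.24, 0.00711). Cell proliferation genes were higher without knockout replicate 1 (0.43, 4.48e-08), without both squamous arrays (0.42, 2.64e-06), with array weights (0.41, 0.000502) and with the covariates (0.14, 0.047). Heat shock genes were higher without wild type replicate 3 (0.31, 0.000198) and knockout replicate 1 (0.30, 0.00331), without both squamous arrays (0.33, 0.00795), with the covariates (0.33, 0.00125) and with no filter on dim probes (0.21, 0.025). Macrophage genes were higher without wild type replicate 3 (0.19, 0.0221) and with array weights (0.32, 0.00916), oxidative phosphorylation genes with no filter (0.18, 0.025) and adipocyte genes among the brightest 25% of probes (0.21, 0.0351). Erythrocyte genes were lower without wild type replicate 3 (-0.69, 0.0144) and without knockout replicate 3 (-0.29, 0.0226). Relative to other genes, antrum and duodenum genes were lower without wild type replicate 1 (0.19, 0.0442) and without knockout replicate 2 (0.01, 0.0244), and fibroblast genes without wild type replicate 2 (-0.04, 0.031), while fibroblast genes were higher with array weights (0.35, 0.000895).

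The neighbours of Lasp1 on chromosome 11 fixed as a list did not shift together (49 genes, median 0.10, camera adjusted p = 0.358). Single genes of the region did differ. Among the 100 measured genes on each side of Lasp1, in the gene order of the GRCm38.p6 annotation, 2 of 200 had an unadjusted p under 0.01, against 19 of 11651 other genes (Fisher's exact test, two-sided p = 0.0482). With 50 and with 200 genes on each side Fisher's exact test gave p = 0.163 and 0.157. The 2 genes were Elobl, 71 measured genes away on one side, and Smarce1, 30 away on the other. After quantile normalization 8 of 200 did, against 22 of 11651 (Fisher's exact test, p = 2.43e-08). Higher in the knockout were Elobl (2 on the quantile-normalized scale), Krt12 (1.48), Acsf2 (0.58) and Smarce1 (0.50), and lower were Rapgefl1 (-0.94), 2210409E12Rik (-0.76), Rsad1 (-0.62) and Tom1l1 (-0.46). Of these, only Elobl passed the test over all probes. With the title-number set as a block 10 of 200 against 185 of 11651 had such a value (Fisher's exact test, p = 0.00174).

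**Figure D4:**
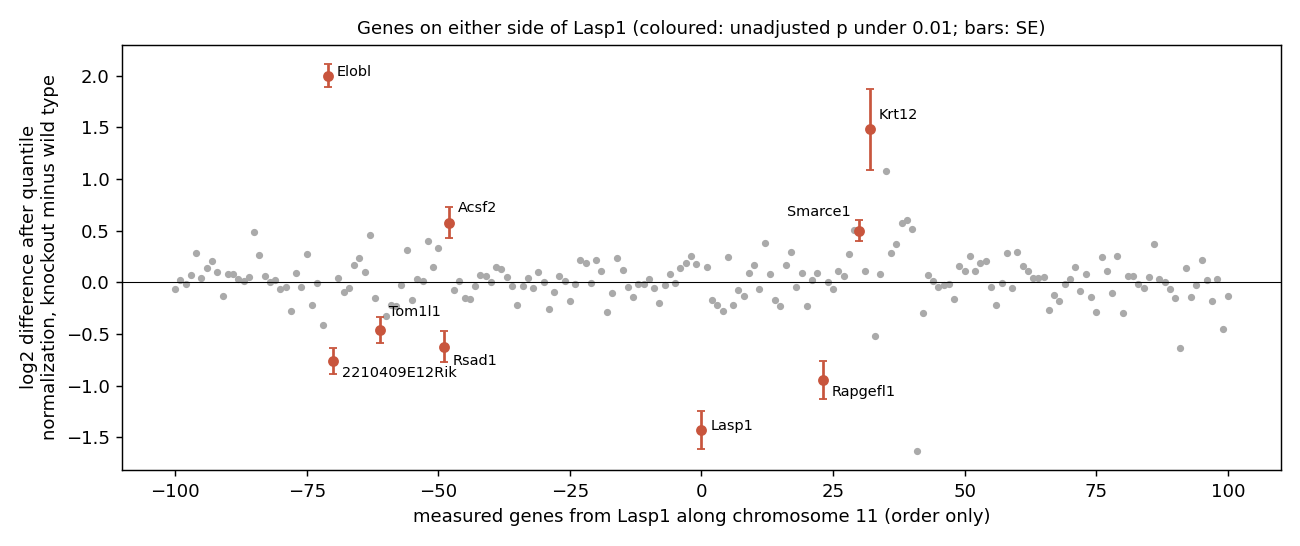
Log2 difference after quantile normalization for the 100 measured genes on each side of Lasp1 on chromosome 11, in gene order (horizontal axis, number of measured genes from Lasp1), with genes of unadjusted p under 0.01 in red with their SE. The 8 such neighbours lie between Elobl (71 genes before Lasp1) and Krt12 (32 genes after), 4 higher and 4 lower in the knockout.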

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

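The block for title numbers, the covariates, the omission of both squamous arrays, normexp and the estimated correlation under each alternative were chosen after the result was seen. Of the probes changed in Lasp1 knockout against wild type, 2 in the reported fit, 0 passed with the brightest 25% of probes, 0 with the replicate block, 0 without both squamous arrays, 0 to 3 in leave-one-out fits, 8 with squamous and pancreatic scores as covariates (5 higher, 3 lower), 1816 with array weights (1600 higher, 216 lower) and 42 at an unadjusted p under 0.01 (37 higher, 5 lower). At an unadjusted p under 0.05 the limma fits with 0 calls had 138 probes (brightest 25%), 753 (replicate block), 521 (without the squamous arrays) and 98 to 1232 (leave-one-out). That filter leaves out Elobl and ILMN_2993962 as too dim, and leaving out arrays or adding a block leaves fewer residual degrees of freedom. Array weights ran from 0.142 for wild type replicate 3 to 38.8 for wild type replicate 2, a ratio of 273, so that fit rests largely on 1 array. The cause of the other differences was not tested. The Lasp1 level was past the threshold at -1.48 with cyclic loess, -1.45 with array weights and -1.47 with the covariates, and ran from -1.51 to -1.19 in leave-one-out fits. Of the gene lists, 0 passed with an estimated correlation, 0 with fry and 0 with mixed fry, and 10 to 13 in leave-one-out fits. The chief cell list turned upward with array weights (adjusted p = 0.898) and without wild type replicate 3 (0.867, leave-one-out 6.94e-05 to 0.867). The pancreatic acinar cell list did so without that array (0.208, leave-one-out 2.44e-25 to 0.208) and with the covariates (0.92), which include its own score and so remove its difference by construction.

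Replicate numbers did not pair the arrays: deviations from the group means correlated at 0.0445, -0.299 and 0.527 for same-numbered arrays. Median scaling and the floor of 50 left every value as it was and so test nothing. The trend and robust variance models play no part in camera, so 4 of the 23 alternatives could not alter the lists. Interferon-response and immediate early genes passed camera with its preset correlation in the same direction under the 19 others. Background limits the folds of dim genes: Elobl gave 2.64 with normexp against 2.06.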

Other observations

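The tests of array scaling, of single probes and of the title-number sets were chosen after the result was seen. The gastric mucosa arrays also differed by the number in their titles. With genotype in the model, 164 probes passed the limma test between arrays numbered 1 to 3 and 4 to 6, of which 154 were higher on the first set and 10 on the second. After quantile normalization 631 passed, 260 higher on the first set and 371 on the second, so the balance of directions depends on the scaling. Genes of fatty acid use were high on arrays 1 to 3: Acot1 by 15.1-fold (adjusted p = 0.000772), Angptl4, an inhibitor of lipoprotein lipase, by 4.12-fold (adjusted p = 0.00661), and Pdk4, the kinase that shuts pyruvate dehydrogenase, by 3.63-fold (adjusted p = 0.0299). The fixed list of fatty acid oxidation genes was lower on arrays 4 to 6, with a median log2 difference of -0.62 and 3 of 15 members past the threshold (camera adjusted p = 0.00125, adjusted p = 0.616 with an estimated correlation, fry adjusted p = 0.0284). Other lists passed camera too. Lower on arrays 4 to 6 were smooth muscle (-1.29, adjusted p = 1.31e-05) and forestomach squamous genes (-2.74, 0.00108). Higher were pancreatic acinar (4.43, 1.42e-18), heat shock (0.28, 1.16e-06), cell proliferation (0.24, 1.16e-06), chief cell (0.25, 2.86e-05), endoplasmic reticulum stress (0.06, 0.000765), cholesterol (0.0041, 0.0311) and enteroendocrine genes (0.0025, 0.0344). None of these passed with an estimated correlation (0.585 or more) or fry (0.24 or more).

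Single genes of glutathione and detoxification were also higher on arrays 1 to 3: Slc7a11, the cystine transporter (4.93-fold, adjusted p = 0.00783), Gclc, which makes glutathione (2.92-fold, adjusted p = 0.00965), Aldh3a1 (2.86-fold, adjusted p = 0.0207), Cyp2b10 (7.03-fold, adjusted p = 0.0215) and Mgst1 (2.33-fold, adjusted p = 0.0295). The fixed list of such genes, which does not hold Slc7a11 or Cyp2b10, had 3 of 24 members past the threshold and a median of -0.49 on arrays 4 to 6 (camera adjusted p = 0.00161, adjusted p = 0.867 with an estimated correlation, fry adjusted p = 0.24). Cirbp, a cold-inducible RNA-binding protein, was 5.01-fold higher on arrays 1 to 3 (adjusted p = 0.0282). Higher on arrays 4 to 6 were Sprr2f (log2 2.37, adjusted p = 0.0282), Sostdc1 (1.57, adjusted p = 0.0184) and Egf, the epidermal growth factor (1.27, adjusted p = 0.0282).

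For this difference between title-number sets, quantile normalization left 631 probes past the threshold, 131 of them shared with the 164, which argues against array scaling as its whole cause. Squamous or pancreatic tissue in the samples stays open as a source, and the test made of it cannot decide. It compared wild type replicate 1 and knockout replicate 2, both low in those transcripts, over 164 probes chosen on the other 4 arrays. They differed by a median of 0.08 of the difference between sets (0.0618 after quantile normalization). On those 4 arrays, however, the first set carried squamous and the second set pancreatic transcripts. The choice therefore favoured tissue genes, and the low ratio does not give the share due to tissue. Over the 164 probes that passed on all 6 arrays the ratio was 0.70, which their choice pulls towards 1, so it excludes nothing. A processing batch and a difference in feeding, time of day or handling of the mice remain open and could not be separated with these labels, and no biological explanation was tested.

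Pancreatic and squamous transcripts on single arrays may come from neighbouring tissue taken with the mucosa. On wild type replicate 3 all 16 acinar genes exceeded every other array as deposited, by 4.51 log2 at the median and by 4.34 after quantile normalization (where Clps did not, at -0.0208), which argues against scaling. They read 449183 to 647587 there, near that array's maximum of 677045, so the array's range may compress these gaps. Islet hormone genes, set as a test before their values were seen, had a median gap of 0.248, under the 0.5 set as evidence against pancreas tissue; the test was judged unable to decide only afterwards, because 2 of the 4 genes (Ppy and Iapp) stayed within background on every array. The other 2 went apart: Ins2 read 8941 there and at most 863 elsewhere, and Gcg read 6716 there and 8644 on knockout replicate 3, which also carried acinar transcripts (Cela2a 58913, Ctrl 14296), so Gcg argues neither way. For wild type replicate 2 and knockout replicate 1, a second squamous list of 17 genes fixed before its values were seen was higher on both by a median of 0.941 log2 (14 of 17 above all other arrays, Rptn at 50432 and 112686), which is consistent with forestomach tissue in those samples, and the first list kept a gap of 2.42 after quantile normalization, against scaling; of the acinar list, Rnase1 and Cpb1 are also in the chief cell list, Clps read 513831 to 635559 on all arrays, and no biological explanation was tested.

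A candidate explanation for the cluster of differing genes around Lasp1 is DNA of another strain inherited with the deleted allele. The test set beforehand, a higher share of genes with p under 0.01 near Lasp1, gave a Fisher's exact p of 0.0482 on only 2 genes (0.163 and 0.157 with 50 and 200 genes on each side). After quantile normalization it gave 2.43e-08 (4.66e-06 and 4.78e-06 with 50 and 200 genes). At an unadjusted p under 0.05 in the deposited values, 14 of 200 near genes differed, against 243 of 11651 (Fisher's exact p = 0.000116). All these tests treat genes as independent. A base difference under single probes, which would alter binding and not level, cannot be told apart: of the 2 genes tested only Smarce1 had a second probe, with a log2 ratio of 0.891 to the first. Of the 8 genes found after quantile normalization, 4 had a second probe. In the deposited values the ratios were 1.03 for Krt12, 0.891 for Smarce1, 0.466 for Rsad1 and -0.317 for Rapgefl1. After quantile normalization the second and first probes differed by 1.55 and 1.48, 0.43 and 0.50, -0.31 and -0.62, and 0.09 and -0.94 for these genes. An effect of the missing Lasp1 on its neighbours also stays open, as it was not tested.

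With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split gave 2 probes, and 2 splits gave as many or more, the real one included. The other was the split of title numbers 1 to 3 against 4 to 6, with 10 probes, which points to that structure of the samples; with it as a block, genotype gave 3 probes. For gene lists the real split gave 11 and the highest other split 15, and 5 of the 10 splits gave as many as the real one.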
